A study of Mus musculus with 10 samples.

How the data were processed

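The series holds 10 RNA libraries from the male germline of mice that carry or lack Ago4, a gene for an Argonaute protein, a family that binds small RNAs. Per the labels, 8 libraries hold mRNA, from pachytene spermatocytes and leptotene/zygotene spermatocytes of mice aged 70 days and from whole testes at day 3 and day 8, with 1 library per genotype in each. The other 2 libraries hold small RNA of pachytene cells and are not analysed here. RNA was taken with Trizol and made into libraries with a TruSeq RNA kit, per the labels' protocols, which name no step that keeps the strand, so overlapping and antisense genes cannot be told apart by strand.

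The values used come from 4 tables of the authors' own comparisons, 1 each for pachytene, leptotene/zygotene, pre-meiotic and day 3 material, with 36806 rows in each. Per the submitters' processing notes, the tools were TopHat 1.3.0, Bowtie 0.12.7, Cufflinks 1.1.0 and Cuffdiff. The genome build is not given in the sources used here, and coordinates are printed as the tables give them, counted from 1. A locus in these tables can cover several overlapping genes. Per the file headers, the authors deposited for each gene a log2 fold change, a test statistic, a p-value and a q-value. The test statistic is a score made by the authors with Cuffdiff from the same pair of conditions, per the file headers and the submitters' processing notes. These values were copied, not recomputed. Where the level was 0 in 1 condition, the authors' log2 fold column holds an extreme value that stands for an infinite ratio. The same tables hold FPKM per condition, per the file headers.

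The tables name their 2 conditions only by number, and no label says which number stands for which genotype. Nothing says either that the order is the same in all 4 tables. The 8 columns of FPKM per condition were therefore assigned to no library and not used. Every fold is given as the second condition relative to the first condition of its own table, with no genotype attached, and none was inferred from the level of Ago4. The stage of a table is known from the table's name, and the pre-meiotic table was assigned to neither age of whole testis. The day 8 testes are the only mRNA material that no table names. The plan written before the data were examined assumed FPKM per genotype. Its floors of FPKM, pseudocounts and levels per library were not applied, and the authors' log2 fold, statistic, p-value and q-value were used in their place.

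Genes entered where the table marked the test as done and the ratio was finite and not 0. The error of each log2 fold was taken as the size of the log2 fold divided by the size of its test statistic and is called the implied error. It stands for the counting and modelling error that Cuffdiff gave for 2 libraries, not for the spread between animals. Depth is unknown, since no counts per library were used, and the implied error is the only measure of precision. With 1 library per genotype and stage there is no replicate check, and the authors' tests compare 2 libraries, not 2 genotypes. A gene is called where the authors' q-value is at most 0.05.

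A total of 26 gene lists, fixed before the data were examined, covered pathways, germ cell stages and other cell types. Some lists share genes and are not independent. Sycp3, Spo11, Prdm9 and Meiob are on both the meiotic entry list and the leptotene and zygotene list. Their members were found by the table's symbol or by the current symbol of the gene ID, which 31840 of the 36806 IDs matched. For each list with at least 5 measured members, the median log2 fold was given with its 95% order-statistic interval, which is binomial and over genes, and with its percentile among 10000 random lists of the same size. The random lists were drawn with replacement and matched on implied error in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5, which chance alone would give in 5% of lists. There were 104 pairs of list and table, and the epididymis list at day 3 had too few measured members for a percentile. The percentile describes these libraries and is not a test of genotypes. Counts of called list members are given over all genes and adjusted over the list alone by the Benjamini-Hochberg method. X-linked genes and each autosome were treated in the same way, with autosomal genes as the pool.

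Named genes follow a rule set in outline before the data were examined and adapted after it, because FPKM could not be used. The rule takes Ago4, the 6 highest and 6 lowest log2 folds among called genes without predicted or clone names, the 5 highest and 5 lowest called X-linked genes with the same names left out, Y-linked genes, and up to 4 members of each list farthest from 0. Other called list members, and genes called in at least 3 tables, were chosen after their values were seen. Not every called list member has its value reported here.

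The alternatives set before the data were examined that could be run were a stricter q-value, random lists without matching, means in place of medians, centring on the median of all genes, no subtraction of the autosomal median from the X-linked median, and an X-linked set without multicopy families or without predicted names. Alternatives added after seeing the data were an implied error of at most 0.5, infinite ratios kept, called genes with at least a 2-fold difference, random lists matched also on locus span, and a comparison of genes with other than predicted names on both the X and the autosomes, and the same with only Rik names left out. The calculations ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 and were tested on simulated folds drawn with each table's own implied errors. In each simulation 200 genes with implied errors under 0.5 were changed, by 2-fold or 4-fold. The 2-fold changes were called in 41% (pachytene, 20730 genes), 55% (leptotene/zygotene, 18368 genes), 78% (pre-meiotic, 18968 genes) and 62% (day 3, 22590 genes), and 4-fold changes in 95%, 96%, 98% and 100%. Of 40 unchanged lists of 20 genes, 1, 1, 1 and 2 stood apart, and all 40 lists shifted by 0.5 did so in each table. These lists held random genes with independent errors, so they do not test lists whose genes vary together.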

Results

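Gene expression was measured by RNA sequencing in Ago4+/+ and Ago4-/- littermates of the C57BL/6 mouse strain. The samples were pachytene spermatocytes, leptotene/zygotene spermatocytes and whole young testes. Leptotene, zygotene and pachytene are successive stages of the first meiotic prophase, and the X and Y chromosomes are silenced at pachytene. By its title, the series concerns the start of meiosis and sex chromosome silencing. Each genotype and stage had 1 library, so no value has a replicate error, and the errors given are those implied by the authors' test. Folds compare the second condition with the first condition of each table, and which of them is Ago4-/- is not given in the sources used here. Between 18368 and 22590 genes per table were tested with a finite ratio. The median implied error of a log2 fold was 0.46 at pachytene, 0.41 at leptotene/zygotene, 0.25 in the pre-meiotic table and 0.31 at day 3.

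Ago4 is listed under its older symbol Eif2c4 (ENSMUSG00000042500, chromosome 4, 126166785 to 126210716) and had a higher value in the second condition of all 4 tables. Its log2 fold in the authors' deposited table was 1.48 at pachytene (implied error 0.29, q = 0.000147) and 0.96 at leptotene/zygotene (implied error 0.28, q = 0.0385). For pre-meiotic material the authors' deposited table gave 0.40 (implied error 0.31, q = 0.672), and for day 3 it gave 0.46 (implied error 0.36, q = 0.420). The last 2 did not pass the threshold. The deleted part of the gene is not given in the sources used here, so these values were not used to tell which condition is which genotype.

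In the pachytene table, genes that respond quickly to stimulation and stress were higher in the second condition, and so were markers of blood vessels, muscle and connective tissue. The list of immediate early and heat shock genes was fixed as a check of sample quality. These values cannot tell transcripts of spermatocytes from those of other cells in the preparations, and a difference in purity or handling was not tested. No list of germ cell stages stood apart in the main setting. The spermatid list (median -0.088) did so on the lower side by its mean (-0.17, percentile 0.76) and against random lists matched also on locus span (percentile 0.77), and the undifferentiated spermatogonia list (median 0.29) on the higher side without matching (percentile 97.96). Of 17 immediate early and heat shock genes, 9 rose and none fell, and 14 rose when adjusted over the list alone. Their median log2 fold was 1.35 (interval 0.85 to 1.58, percentile 100). In the authors' deposited table, the immediate early response gene Ier3 had a log2 fold of 2.36 (q = 0.000573) and Zfp36, which promotes mRNA decay, 2.30 (q = 6.74e-09). The transcription factors Atf3 and Fos were at 2.29 (q = 2.49e-06) and 2.21 (q = 1.88e-11) in the authors' deposited table. Among 14 endothelial genes 3 rose, and 7 did so adjusted over the list alone (median 1.32, interval 0.15 to 2.34). They were the adhesion molecule Pecam1 at 2.48 (q = 0.00111) and the receptors Tie1 at 2.34 (q = 0.0272) and Kdr at 2.11 (q = 0.0120) in the authors' deposited table. Of 11 peritubular myoid and smooth muscle genes 3 rose, and 4 did so adjusted over the list alone (median 0.80, interval -0.02 to 1.49). Per the authors' deposited table they were desmin, Des, at 2.22 (q = 0.0135), smooth muscle actin, Acta2, at 1.49 (q = 0.0261) and smooth muscle myosin, Myh11, at 1.26 (q = 0.0309).

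Stroma and extracellular matrix genes were also higher at pachytene (median 0.63, interval 0.30 to 1.38), with 2 of 15 called, and 6 higher and 1 lower adjusted over the list alone. The called genes encode collagens, Col4a2 at 1.89 (q = 0.0274) and Col1a2 at 1.35 (q = 0.0489) in the authors' deposited table. On the list for epididymis and other adjacent tissue, 3 of 6 genes rose, and 4 did so adjusted over the list alone (median 1.29, interval -0.07 to 1.42, or 0.67 with infinite ratios kept). In the authors' deposited table these were Svs2 at 1.42 (q = 6.93e-09) and Svs4 at 1.32 (q = 7.76e-06), both of the seminal vesicle, and Pate4 at 1.25 (q = 0.0149). Erythrocyte genes had a median of 1.80 (interval -1.25 to 2.63), with 0 of 6 called and 3 higher and 1 lower adjusted over the list alone. Sertoli cell genes had a median of 0.37 (interval 0.11 to 0.56), with 0 of 21 called and 0 adjusted over the list alone. By its mean (0.30, percentile 97.1) the Sertoli list did not stand apart.

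Among genes of the leptotene and zygotene stages, 5 of 27 fell in the second condition of the pachytene table and none rose. Adjusted over the list alone, 5 fell and 1 rose, and the list median of 0.01 (interval -0.29 to 0.23, mean -0.04) did not stand apart. Tex15, needed for meiotic recombination, was at -1.54 (q listed as 0) in the authors' deposited table. The synaptonemal complex genes Sycp2 and Sycp1 were at -1.14 (q = 4.13e-12) and -1.03 (q = 0.00324), and the cohesin genes Smc3 and Smc1b at -1.0 (q = 0.0184) and -0.95 (q = 0.00128), in the authors' deposited table. Tex15, Sycp2 and Smc1b each span at least 60610 bp. Loci of that size with implied errors of at most 0.5 had a median of -0.045 in this table. No member of the pachytene spermatocyte, piRNA pathway or spermatogonia lists was called over all genes.

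In all, 354 of 20730 genes were called at pachytene, 136 higher and 218 lower. Leaving out predicted and clone names here and for the other tables, the highest in the authors' deposited table were the peptidase gene Trhde (log2 fold 4.93, implied error 0.81), the glycosyltransferase gene B3gnt2 (4.55, error 1.21) and the antigen-presenting gene H2-Ab1 (3.70, error 0.38). Lowest in the authors' deposited table were the serotonin receptor gene Htr5b (-5.77, error 1.48), the histidine-degrading Hal (-4.28, error 1.07) and the ribosomal protein gene Rps18 (-3.81, error 0.47). Altogether 7 lists stood apart, and the other 19 had medians from -0.15 to 0.38. The highest of these, the interferon list (3 of 19 called, 2 higher and 1 lower, 3 and 1 adjusted over the list alone), stood apart by its mean (0.72, percentile 99.8) and without matching (percentile 99.6). The 19 were the Argonaute and microRNA, piRNA, retinoic acid, undifferentiated and differentiating spermatogonia, leptotene and zygotene, pachytene, spermatid, sex chromosome silencing, Y-linked, X-linked housekeeping, X-linked multicopy, Rhox, p53, interferon, histone, cell cycle, Leydig and macrophage lists.

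In the leptotene/zygotene table, stress response, blood and muscle genes were also higher in the second condition. Here too, whether they came from spermatocytes or from other cells in the preparations was not tested. Of 17 immediate early and heat shock genes 9 rose, and 12 rose and 1 fell adjusted over the list alone (median 1.11, interval 0.57 to 1.49). Examples from the authors' deposited table are Zfp36 at 1.81 (q = 1.84e-11), Fos at 1.54 (q = 2.88e-06) and Junb at 1.52 (q = 0.00151). Among 7 erythrocyte genes 4 rose, all of them globin genes, and 6 rose and 1 fell adjusted over the list alone (median 3.05, interval -0.43 to 4.03). The globin genes Hbb-b2 and Hba-a2 were at 3.58 (q = 6.50e-12) and 3.05 (q = 1.18e-10) in the authors' deposited table. Of 11 myoid and smooth muscle genes 6 rose, and 9 did so adjusted over the list alone (median 2.01, interval -0.04 to 2.84). Per the authors' deposited table, Des was at 4.77 (q = 0.00167), the tropomyosin gene Tpm2 at 2.84 (q = 0.0147) and Acta2 at 2.17 (q = 1.78e-07).

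Further lists stood apart at leptotene/zygotene on the same side, while the Sertoli, Leydig and epididymis lists did not stand apart and had medians of -0.11, -0.20 and -0.04. Stroma genes had a median of 0.93 (2 of 15 called, both higher, 2 adjusted over the list alone), and macrophage and leukocyte genes one of 0.49 (3 of 14 called, all higher, 3 adjusted over the list alone). Endothelial genes had a median of 1.16 (1 of 14 called, 2 higher adjusted over the list alone), and interferon response genes one of 0.77 (0 of 19 called, 0 adjusted over the list alone). At implied errors of at most 0.5 the stroma median was 0.50 and the macrophage median 1.13, and both lists still stood apart. By the authors' deposited table, Col4a2 was at 2.38 (q = 2.94e-05), H2-Ab1 at 2.59 (q listed as 0) and Kdr at 2.32 (q = 0.0269). Genes of the piRNA pathway, which protects the germline from transposons, were lower, with 16 of 18 below 0 (median -0.25, interval -0.44 to -0.08, percentile 0.55). Of these 2 fell, and 4 did so adjusted over the list alone. The called genes were Piwil1 at -0.59 (q = 0.0402) and Tdrd7 at -0.50 (q = 0.0165) in the authors' deposited table. Against random lists without matching, the piRNA list lay at percentile 6.2 and did not stand apart.

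No gene of the leptotene and zygotene list itself was called at leptotene/zygotene (median -0.01, interval -0.12 to 0.11, mean 0.02), and 2 rose and 1 fell adjusted over the list alone. The calls came to 405 of 18368 genes, 150 higher and 255 lower. Highest among named genes in the authors' deposited table were Pkhd1, a gene of polycystic kidney disease (log2 fold 6.203, error 1.79), and the transcription factor gene Ebf1 (5.20, error 1.39). Lowest in the authors' deposited table were the NLR family gene Nlrp4e (-5.84, error 1.57), Faim3 (-5.53, error 1.52) and the transcription factor gene Hlf (-5.53, error 1.51). Altogether 8 lists stood apart, and the other 18 had medians from -0.30 to 0.14. The latter were those that did not stand apart at pachytene, without the piRNA, interferon and macrophage lists and with the Sertoli and epididymis lists.

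In the pre-meiotic table, genes of meiotic entry and of the leptotene and zygotene stages were lower in the second condition. Of 28 leptotene and zygotene genes 27 were below 0 and 10 fell, or 15 adjusted over the list alone, and none rose. The median was -0.45 (interval -0.59 to -0.35, percentile 0.00). Farthest from 0 among called members in the authors' deposited table were Tex12, of the synaptonemal complex, at -1.05 (implied error 0.25, q = 0.00458) and the histone methyltransferase Prdm9, which places recombination hotspots, at -1.004 (error 0.26, q = 0.0130). The recombinase Dmc1 was at -0.90 (error 0.15, q = 1.34e-06) and Sycp3, of the synaptonemal complex, at -0.89 (error 0.12, q = 1.21e-10) in the authors' deposited table. Spo11, which makes the meiotic DNA breaks, was at -1.43 with an error of 0.68 in the authors' deposited table and was not called (q = 0.431).

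Of 18 genes of differentiating spermatogonia and entry into meiosis 5 fell, and 7 did so adjusted over the list alone (median -0.32, interval -0.77 to 0.05, percentile 0.00). Stra8, the retinoic acid target needed to enter meiosis, was at -0.66 (error 0.09, q = 8.29e-10) in the authors' deposited table. Also called were Gm1564, now named Meioc, at -0.95 (q = 1.32e-09) and the X-linked Esx1 at -0.77 (q = 0.00769) in the authors' deposited table, besides Prdm9 and Sycp3. The undifferentiated spermatogonia list had a median of 0.16 (interval -0.24 to 0.45), and its percentile of 97.49 lay just inside the limits. Against random lists without matching (percentile 97.6) and by its mean (0.36, percentile 99.9) it stood apart on the higher side. At implied errors of at most 0.5 its median was -0.00044 (interval -0.47 to 0.41, percentile 52.7, 15 genes). Of its 20 genes 1 was called, Taf4b at -0.47 (q = 0.00337) in the authors' deposited table, and 1 rose and 3 fell adjusted over the list alone.

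**Figure D1:**
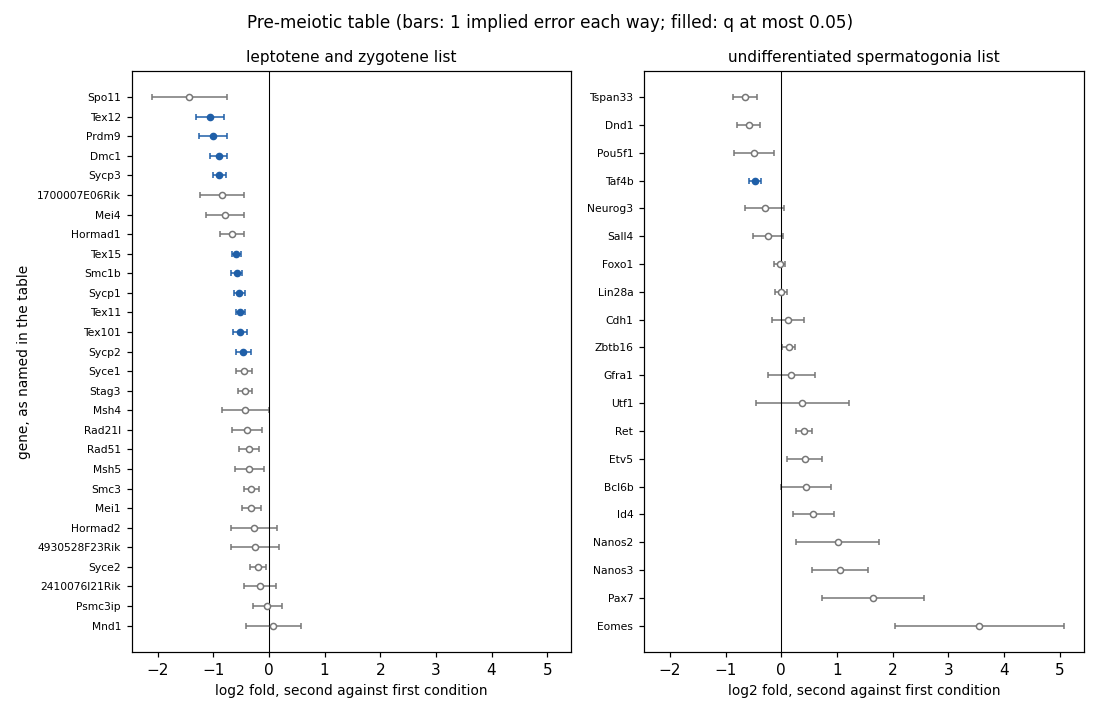
Log2 fold of the second against the first condition (x axis) for each measured member (y axis) of the leptotene and zygotene list and of the undifferentiated spermatogonia list in the pre-meiotic table. Points are the authors' values, bars reach 1 implied error each way, and filled points have q of at most 0.05: 10 of 28 genes in the first list, all below 0, and 1 of 20 in the other.

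Retinoic acid starts meiosis, and genes of its pathway had a median of -0.03 (mean -0.18) in the pre-meiotic table, with 2 of 22 fallen (2 adjusted over the list alone). Among them was the retinal dehydrogenase gene Aldh1a2 at -0.46 (q = 0.00993) in the authors' deposited table. The piRNA list had a median of -0.01 (interval -0.25 to 0.15, mean -0.12), with 2 of 19 called, both lower, and 2 adjusted over the list alone. A further group of lists stood apart on the lower side. The sex chromosome silencing list among them shares Hormad1 and Hormad2 with the leptotene and zygotene list. Pachytene genes had a median of -0.21 (0 of 22 called, 0 adjusted over the list alone), and sex chromosome silencing genes one of -0.14 (0 of 23 called, 5 lower adjusted over the list alone). Cell cycle genes had a median of -0.16 (0 of 24 called, 2 lower adjusted over the list alone). The list for epididymis and other adjacent tissue had one of -0.36 (2 of 5 called, both lower, 3 adjusted over the list alone), with Svs2 at -0.60 (q = 3.31e-07) in the authors' deposited table. By their means the pachytene (-0.26, percentile 3.44) and cell cycle lists (-0.09, percentile 3.01) did not stand apart. Without matching, neither did the silencing (percentile 3.22) and epididymis lists (percentile 3.50).

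Of 8 lists of somatic cells, 5 stood apart on the higher side in the pre-meiotic table. Stroma genes had a median of 0.24 (interval 0.17 to 0.37), with 3 of 16 called, all higher, and 11 adjusted over the list alone. Per the authors' deposited table, the collagen genes Col1a1 and Col1a2 were at 0.42 (q = 0.00109) and 0.37 (q = 2.95e-05). Leydig cell genes had a median of 0.25 (0 of 15 called, 1 higher adjusted over the list alone), and immediate early genes one of 0.26 (1 of 17 called, higher, 1 adjusted over the list alone). Myoid genes (median 0.13, 1 of 11 called, higher, 1 adjusted over the list alone) and Sertoli cell genes (median 0.09, 1 of 21 called, higher, 1 adjusted over the list alone) stood apart too. Without matching these lay at percentiles 88.7 and 87.8 and did not. As means the Leydig and Sertoli values were 0.43 and 0.17, and both lists still stood apart. Erythrocyte genes had a median of 0.71 (interval -4.36 to 1.12), with 4 of 6 called, all globin genes and higher, and 5 higher and 1 lower adjusted over the list alone. Their mean of -0.09 had the opposite sign, and Slc4a1 was at -4.36 with an error of 1.77 in the authors' deposited table.

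The pre-meiotic table held 226 called genes of 18968, 91 higher and 135 lower, of which 45 differed at least 2-fold. Highest among named genes in the authors' deposited table were the ribosomal protein gene Rpl29 (log2 fold 3.58, error 0.30), the muscle gene Ky (3.46, error 0.86) and the respiratory complex I gene Ndufs5 (3.08, error 0.43). Lowest in the authors' deposited table were the small nuclear RNA 7SK (-3.48, error 0.71) and the mitochondrial gene Lyrm7 (-3.26, error 0.71). Altogether 12 lists stood apart, and the other 14 had medians from -0.52 to 0.22. The lowest of these, the histone list, lay at percentile 0.08 without matching, but at 0.020 (percentile 45.8) with infinite ratios kept. The macrophage list (0.22) stood apart by its mean (0.40, percentile 99.2) and without matching (percentile 99.2). Without matching, the interferon (percentile 99.2), spermatid (percentile 0.49) and X-linked multicopy lists (percentile 1.11) did so too. The 14 were the Argonaute and microRNA, piRNA, retinoic acid, undifferentiated spermatogonia, spermatid, Y-linked, both X-linked, Rhox, p53, interferon, histone, macrophage and endothelial lists.

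In the whole testes of day 3, far more genes were called, long genes were lower in the second condition, and so were germ cell genes. Of 22590 genes 3486 were called, 1137 higher and 2349 lower, of which 1348 differed at least 2-fold. Spearman's correlation of log2 fold with locus span was -0.49 across 11394 genes with an implied error of at most 0.5 and a locus of their own. In the order of the other stages above it was -0.14, -0.0063 and 0.00080. These are 4 correlations across genes, which are not independent replicates. The median log2 fold at day 3 was 0.36 for loci of up to 3586 bp and -0.42 for loci of at least 58740 bp.

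At day 3, 7 of 20 undifferentiated spermatogonia genes fell (7 adjusted over the list alone, median -0.42, interval -1.15 to -0.24, mean -0.67), as did 7 of 18 genes of differentiation and meiotic entry (8 adjusted over the list alone, median -0.64). Of 28 leptotene and zygotene genes 8 fell (9 adjusted over the list alone, median -0.48). So did 8 of 19 piRNA genes (12 adjusted over the list alone, median -0.67) and 7 of 12 Argonaute and microRNA genes (7 adjusted over the list alone, median -0.67). Examples from the authors' deposited table are the spermatogonial transcription factor Zbtb16 at -1.84 (q = 2.43e-06), the receptor Gfra1 at -1.46 (q = 1.02e-08) and Kit, the receptor of differentiating spermatogonia, at -1.21 (q = 0.000427). Eif2c2, now named Ago2, was at -2.28 (q = 3.86e-12) and Dicer1, which cuts microRNA precursors, at -1.11 (q = 2.49e-07) in the authors' deposited table. Against random lists matched also on locus span, these 5 lists still stood apart, at percentiles of 0.58, 0.05, 0.16, 0.03 and 0.38.

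**Figure D2:**
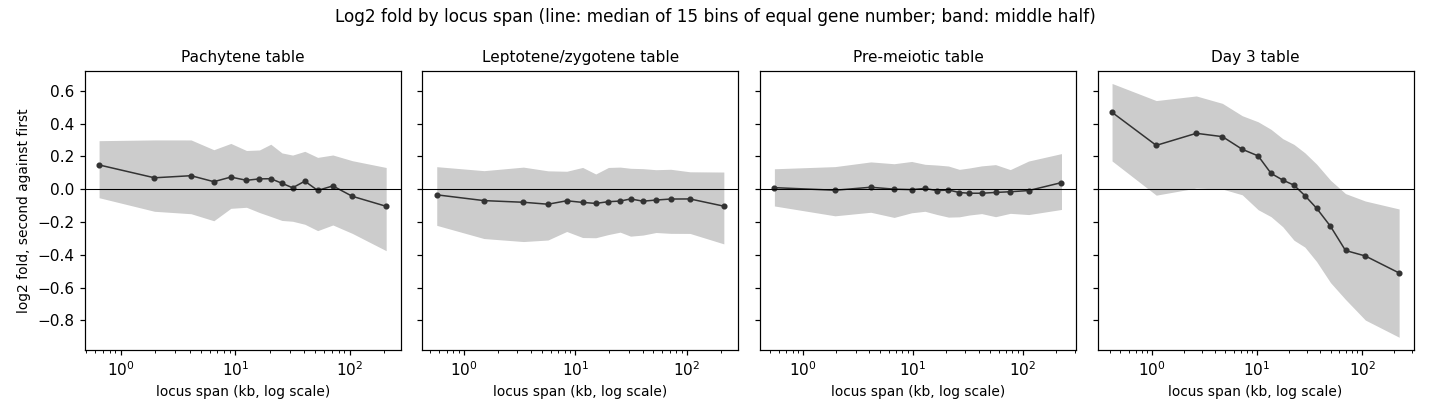
Log2 fold of the second against the first condition (y axis) by locus span in kb (log x axis) in the 4 tables, for genes with an implied error of at most 0.5 and a locus of their own. Points are medians of 15 bins with equal numbers of genes and the band joins their quartiles; the day 3 table falls with span (Spearman's correlation -0.49) and the pre-meiotic table does not (0.00080).

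Genes of the p53 response and apoptosis were higher in the second condition at day 3. Of 20 such genes 7 rose and none fell (7 adjusted over the list alone, median 0.43, interval 0.08 to 0.68). The death receptor Fas was at 1.56 (q = 0.00128), the apoptosis inducer Bbc3 at 1.15 (q = 2.73e-05) and the cell cycle inhibitor Cdkn1a at 0.999 (q = 0.00173) in the authors' deposited table. Macrophage and leukocyte genes rose in 5 of 17 cases (9 adjusted over the list alone, median 0.78, interval 0.26 to 0.91). Among them were Cd74 at 1.105 (q = 0.0179) and the lysozyme gene Lyz2 at 0.95 (q = 0.00874) in the authors' deposited table. Stroma genes had a median of -0.39 (1 higher and 4 lower of 16, 1 and 6 adjusted over the list alone), and interferon genes one of -0.44 (2 of 21 called, both lower, 2 adjusted over the list alone). The X-linked Rhox homeobox cluster had a median of -0.76 (0 of 12 called, 0 adjusted over the list alone). By their means the Rhox (-0.59, percentile 3.99) and stroma lists (-0.30, percentile 3.13) did not stand apart, nor did the Rhox list at implied errors of at most 0.5 (-0.46, percentile 8.05).

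Cell cycle genes (median 0.27, 5 higher and 1 lower of 24, 5 and 2 adjusted over the list alone) and histone genes (median 0.46, 1 of 20 called, higher, 1 adjusted over the list alone) stood apart on the higher side at day 3. Against random lists matched also on locus span they lay at percentiles 94.2 and 95.3 and did not, and without matching the cell cycle list (percentile 95.3) did not either. Highest among named genes in the authors' deposited table were Chi3l3 (log2 fold 7.04, error 2.19) and Zswim2 (6.58, error 2.03). The steroid 21-hydroxylase gene Cyp21a1 was at 3.43 (error 0.37) in the authors' deposited table. Lowest in the authors' deposited table were the potassium channel subunit gene Kcnmb2 (-4.74, error 1.295), the kinase gene Braf (-3.93, error 0.60) and Car10 (-3.91, error 1.34). Altogether 13 lists stood apart, the Y-linked list among them, and the other 12 with enough members had medians from -0.24 to 0.20. Of these the immediate early list (0.20) stood apart by its mean (0.24, percentile 98.6), and the X-linked multicopy list (-0.24) had a mean of -0.06. Against random lists matched also on locus span, the immediate early median moved from percentile 85.7 to 9.79. The 12 were the retinoic acid, pachytene, spermatid, sex chromosome silencing, both X-linked, immediate early, Sertoli, Leydig, myoid, erythrocyte and endothelial lists. The epididymis list had only 2 measured genes, of which 1 rose (1 adjusted over the list alone).

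**Figure D3:**
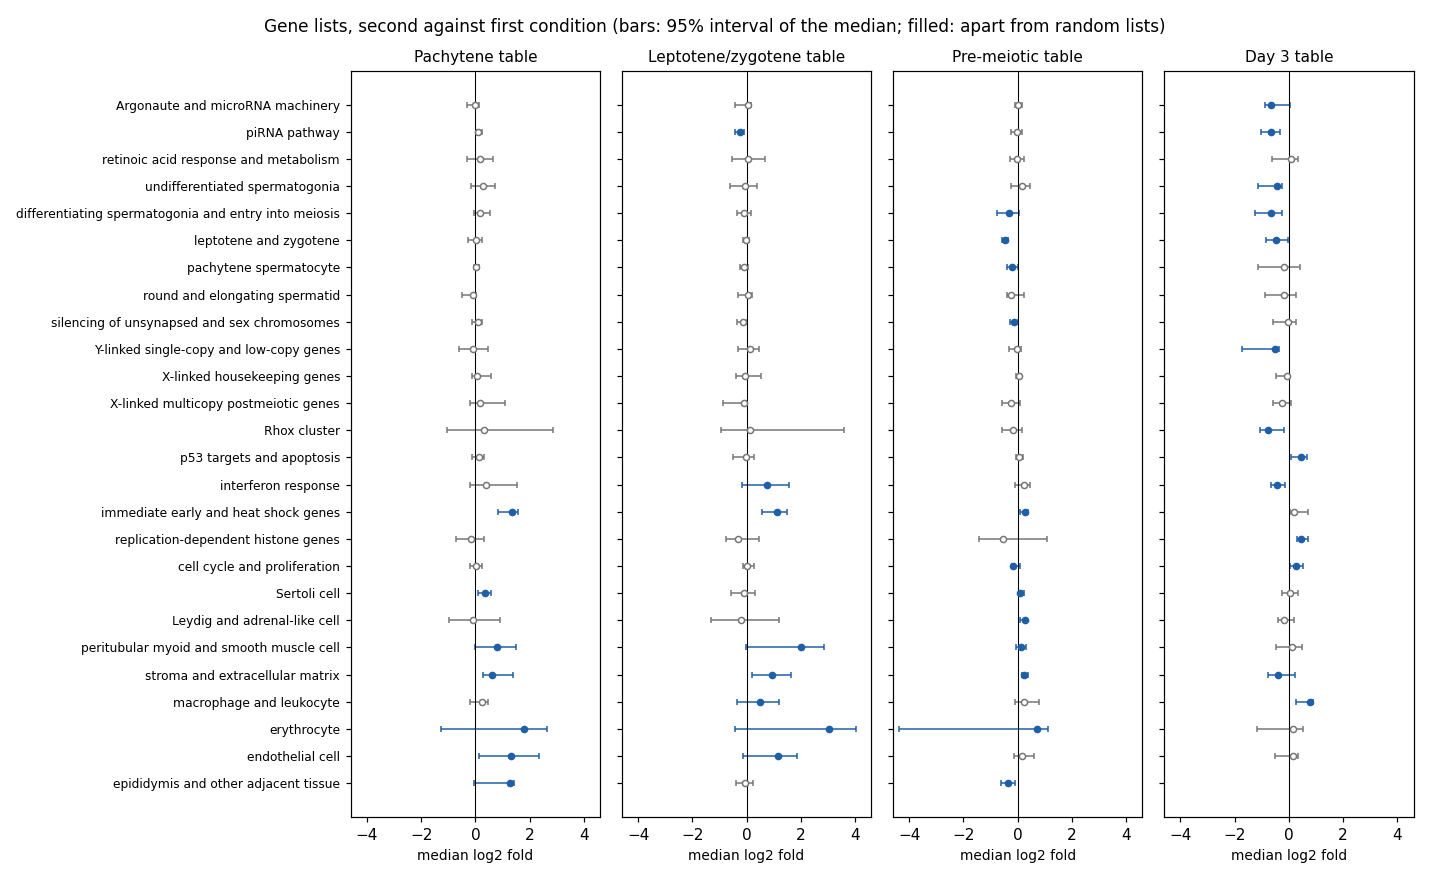
Median log2 fold of the second against the first condition (x axis) for each of the 26 gene lists (y axis) in the 4 tables, with bars for the 95% interval of the median over genes and filled points for lists that stand apart from random lists. The epididymis list has no point at day 3, where only 2 of its genes were measured. The leptotene and zygotene list lies at -0.45 in the pre-meiotic table and at 0.01 in the pachytene table.

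On the X chromosome, the median log2 fold lay below the autosomal median in each table. The difference was -0.059 at pachytene (interval -0.10 to -0.0023, 1191 genes, percentile 0.17) and -0.064 at leptotene/zygotene (interval -0.12 to -0.056, 1054 genes, percentile 0.00). In the pre-meiotic table it was -0.023 (interval -0.041 to -0.0050, 1035 genes, percentile 2.33) and at day 3 -0.077 (interval -0.13 to -0.042, 1359 genes, percentile 0.10). The pre-meiotic value lay near the limit and did not stand apart without multicopy families (percentile 4.45) or at implied errors of at most 0.5 (percentile 4.96). Some autosomes stood apart as well. Chromosome 5 was at -0.034 at pachytene (percentile 0.63) and -0.043 at leptotene/zygotene (percentile 0.14), chromosome 3 at 0.033 at pachytene (percentile 97.8) and chromosome 12 at -0.032 in the pre-meiotic table (percentile 0.90). Chromosomes 1, 2, 7, 16, 17, 18 and 19 stood apart at day 3, with differences from -0.10 to 0.11.

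The X-linked shift depended on which genes were taken. With predicted names left out of the X-linked set, the pachytene value turned to 0.036 (percentile 72.1, 602 genes). The leptotene/zygotene (-0.026, percentile 23.4) and pre-meiotic values (-0.0064, percentile 30.3) then did not stand apart, while the day 3 value was -0.17 (percentile 0.00). At implied errors of at most 0.5 the value was -0.11 at pachytene (346 genes) and -0.10 at leptotene/zygotene (422 genes), both at percentile 0.00. Without subtraction of the autosomal median it was -0.024 at pachytene, -0.13 at leptotene/zygotene and -0.040 at day 3. A division by names was chosen after the values were seen. At pachytene the difference was largest in 89 X-linked genes with Rik names, from the RIKEN cDNA collection. Their median was -0.47 (interval -0.70 to -0.28), against -0.02 in 1838 autosomal genes with such names (percentile 0.00). In 499 X-linked genes with Gm names the difference from autosomal ones was -0.070 (percentile 1.07). At implied errors of at most 0.5 it was -0.17 for Gm names (105 genes) and -0.43 for Rik names (35 genes), both at percentile 0.00. With Rik names left out of the X and the autosomes, the pachytene value was -0.029 (percentile 3.97, 1102 genes) and did not stand apart. Among 206 X-linked genes with other names and implied errors of at most 0.5, the difference from autosomal ones was -0.064 (percentile 0.25).

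Few single X-linked genes were called outside the day 3 table. At pachytene 13 were called, 5 higher and 8 lower, or 1.09% of X-linked against 1.75% of autosomal genes. Without predicted names, the highest of them in the authors' deposited table was the matrix gene Bgn (log2 fold 2.83, q = 0.000341), and the lowest were the kinase subunit gene Phka2 (-1.35, q = 0.0395), the sperm head gene Cylc1 (-1.18, q = 0.0282) and the deubiquitinase gene Usp9x (-0.97, q = 0.0481). At leptotene/zygotene 10 X-linked genes were called, 3 higher and 7 lower. The ubiquitin-activating enzyme gene Uba1 was called in both spermatocyte tables, at -0.73 (q = 0.0149) at pachytene and -0.78 (q = 2.52e-05) at leptotene/zygotene in the authors' deposited table. Pre-meiotic calls included 15 X-linked genes, 1 higher and 14 lower, against 90 higher and 121 lower on autosomes. Among them were Mid1ip1 at -0.81 (q = 0.000542), Fam70a at -0.80 (q = 0.00118) and the meiotic gene Tex11 at -0.52 (q = 2.03e-07) in the authors' deposited table. At day 3, 181 X-linked genes were called, 42 higher and 139 lower. Aff2 was at -2.67, the deubiquitinase gene Usp26 at -2.36 and the ubiquitin ligase gene Huwe1 at -1.91 in the authors' deposited table.

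X-linked housekeeping genes did not stand apart in any table, except by their mean at day 3 (-0.30, percentile 2.22). Their medians were 0.05 at pachytene, -0.06 at leptotene/zygotene, 0.04 in the pre-meiotic table and -0.08 at day 3. At implied errors of at most 0.5 the pachytene value was -0.079, and by the mean the leptotene/zygotene value was 0.11. Over all genes 1, 1, 1 and 10 of 26 were called, and 4, 1, 1 and 10 adjusted over the list alone. No Y-linked gene was called outside the day 3 table. At day 3 all 13 measured Y-linked genes lay below the autosomal median (median -0.46, interval -1.55 to -0.37, percentile 0.88). Of these Usp9y at -1.74 (q = 0.000338) and Uty at -0.46 (q = 0.0292) were called in the authors' deposited table. The fixed Y-linked list had 9 measured genes (2 called, both lower, 3 adjusted over the list alone, median -0.50, percentile 1.72, mean -0.82). It did not stand apart from random lists matched also on locus span (percentile 3.55) or without matching (percentile 3.64), at implied errors of at most 0.5 (-0.46, percentile 2.75) or with infinite ratios kept (-0.48, percentile 3.07).

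**Figure D4:**
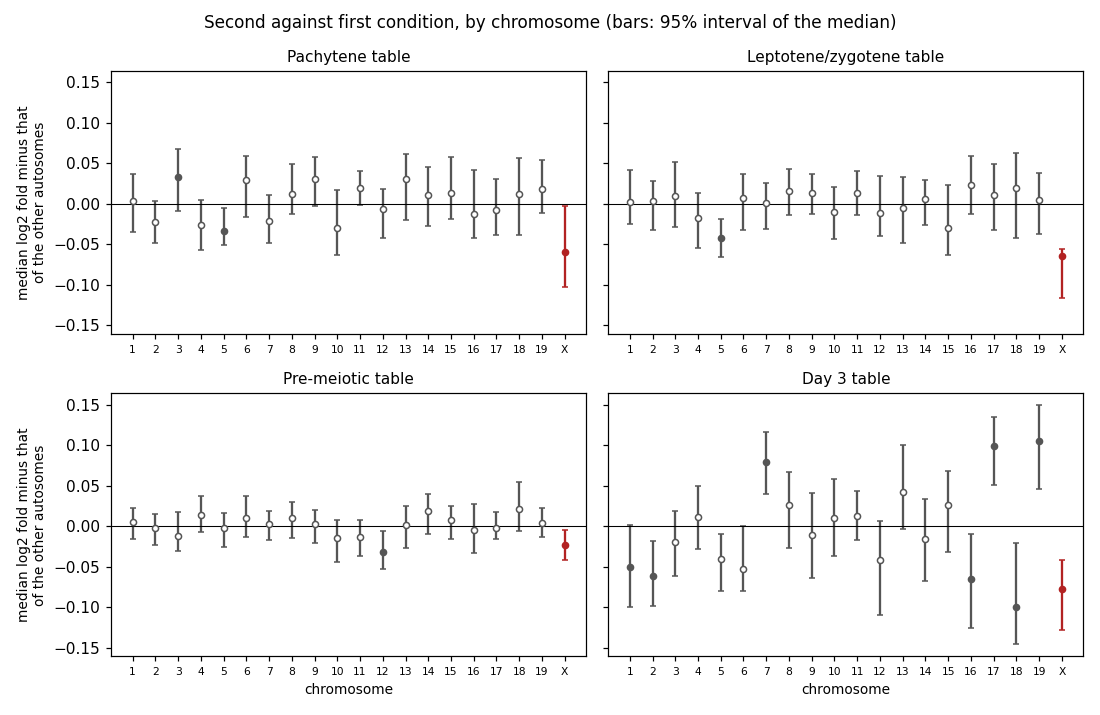
Median log2 fold of the second against the first condition minus that of the other autosomes (y axis) for each chromosome (x axis) in the 4 tables, with the X in red, bars for the 95% interval of the median over genes and filled points for chromosomes that stand apart from random autosomal lists. The X lies at -0.059, -0.064, -0.023 and -0.077, and several autosomes stand apart as well.

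Called genes were shared most between the 2 spermatocyte tables. Of 17949 genes tested in both, 344 were called at pachytene and 405 at leptotene/zygotene, and 111 were called in both, where independent lists would share 7.76. All 111 had the same sign as coded, 41 higher and 70 lower, against 1.09 and 3.03 for independent lists. Pachytene and pre-meiotic tables shared 33 calls (3.84 for independent lists), 25 of them with the same sign. The leptotene/zygotene and pre-meiotic tables shared 17 (4.74 for independent lists), 15 with the same sign. The day 3 table shared 87 calls with pachytene (51.8 for independent lists), 92 with leptotene/zygotene (64.3) and 81 with the pre-meiotic table (39.5). Of these 58, 59 and 42 had the same sign. Over genes with an implied error of at most 0.5 in both, Spearman's correlation of log2 folds across genes was 0.37 between the spermatocyte tables and Pearson's was 0.46. For the other 5 pairs Spearman's lay between 0.022 and 0.27. Whether any library is in 2 tables is not given in the sources used here. Both spermatocyte tables come from mice aged 70 days, and whether they share animals or preparations is not known from the values used. The counts for independent lists are therefore only a reference, and the shared calls are not a replication.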

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

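Tests on somatic cells, Gm-named and Rik-named genes, spermatids, germ cell share, gene length in the pre-meiotic table, precision at day 3 and genes with implied errors of at most 0.5 were chosen only after the result was seen, as were all results with opposite signs named here. Chance alone would put 5% of lists outside the limits if their genes varied independently, and more if they vary together.

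A group of lists stood apart in opposite directions in different tables, and these differences were not tested. Since it is not known that the order of conditions is the same in every table, the signs hold only as coded. Interferon response genes had a median of 0.77 at leptotene/zygotene and -0.44 at day 3. Cell cycle genes had a median of -0.16 in the pre-meiotic table, which did not stand apart by its mean (percentile 3.01), and 0.27 at day 3, which did not when matched also on locus span (percentile 94.2) or without matching (percentile 95.3). Stroma and extracellular matrix genes had medians of 0.63 at pachytene, 0.93 at leptotene/zygotene and 0.24 in the pre-meiotic table against -0.39 at day 3, which did not stand apart by its mean (percentile 3.13). Epididymis and adjacent tissue genes had a median of 1.29 at pachytene and -0.36 in the pre-meiotic table, which did not stand apart without matching (percentile 3.50).

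The X-linked shift at pachytene did not stand apart without Rik names (-0.029, percentile 3.97) and turned without predicted names (0.036, or 0.021 against autosomal genes with such names left out too), while the 206 of these 602 genes with implied errors of at most 0.5 lay at -0.064 (percentile 0.25). More somatic cells in the first condition would lower somatic markers, but 101 of these had a pooled median of 0.46 (interval 0.27 to 0.67) in the opposite direction. Without multicopy families recognized by symbol the X lay at percentile 0.11, which argues against shared reads in those families as the whole cause. Multicopy genes with Gm or Rik names were not left out there, so reads shared among them stay open. X-linked Rik-named genes, at percentile 0.00 of autosomal ones, argue against reads shared between Gm-named pseudogenes and their parent genes as the whole cause. A larger share of spermatids in the first condition stays open, since the spermatid list had a median of -0.088 (interval -0.50 to 0.035) inside the limits, which came to percentile 0.77 with random lists matched also on locus span. The genotype, the difference the design names, stays open too and was untested because the conditions could not be assigned.

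The lower level of leptotene and zygotene genes in the pre-meiotic table was weighed next. A lower share of germ cells of every stage would raise somatic markers. The stroma (0.24), Leydig (0.25), myoid (0.13), Sertoli (0.09) and erythrocyte medians (0.71) were higher, while the epididymis median (-0.36) was lower. Such a share would also lower all germ cell markers alike, and the differentiating spermatogonia (-0.32) and pachytene medians (-0.21) were lower. The undifferentiated spermatogonia list had a median of 0.16. Its interval from -0.24 to 0.45 lies above the interval of the leptotene and zygotene list, -0.59 to -0.35. At implied errors of at most 0.5 the undifferentiated median of -0.00044 (interval -0.47 to 0.41) no longer tells the lists apart, and its only called member was lower. The piRNA genes of the germline, brought in after the values were seen, had a median of -0.013 (interval -0.14 to 0.089) there. That interval lies above the -0.59 to -0.32 of the leptotene and zygotene list. Over all 19 piRNA members the interval was -0.25 to 0.15, and 2 were called, both lower. Because the piRNA list was picked in this way, a lower share of germ cells stays open. A trend with gene length, taken as locus span, is argued against by random lists matched also on locus span, among which the leptotene and zygotene list lay at percentile 0.00. A smaller number of cells that had reached meiosis in the second condition, whether from genotype or from variation between animals, remains a candidate explanation that these tables leave untested.

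The day 3 table held 3486 calls where the others held 226 to 405. By its median implied error of 0.31, above the 0.25 of the pre-meiotic table, finer counting precision alone is argued against. These medians cover different sets of tested genes. The day 3 table also held the most genes with an implied error of at most 0.5, 16816 against 13408 in the pre-meiotic table. A trend of fold with gene length, as a difference in RNA integrity or in unspliced RNA between 2 libraries could give, had the values it needs, since called genes that were lower spanned 60600 bp at the median and those that were higher 7227 bp, a ratio of 8.39, but the pachytene table, with only 354 calls, also passed the bound of 2 with a ratio of 2.24 (1.498 at leptotene/zygotene, 1.12 in the pre-meiotic table), so passing it does not by itself go with many calls. The lower germ cell lists stood apart from random lists matched also on locus span, so the span trend alone does not account for them. Transcript length was not matched, so these lists do not test a difference in RNA integrity. No biological explanation was tested.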

How the results depend on the processing

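Settings other than the stricter q, unmatched random lists, means, centring, no subtraction of the autosomal median, multicopy families and predicted names were chosen after seeing the data. At q of at most 0.01 the calls came to 164 at pachytene, 199 at leptotene/zygotene, 117 in the pre-meiotic table and 2242 at day 3, and 52 were shared between the spermatocyte tables, fewer by construction. With at least a 2-fold difference asked for, 184, 45 and 1348 calls were left in the last 3 tables and 237 at pachytene. For the X, predicted names left out gave 0.036 at pachytene, which turned the sign, and -0.026 and -0.0064 at leptotene/zygotene and in the pre-meiotic table. With such names left out of the autosomes too, these were 0.021, -0.033 and -0.0063, and with Rik names left out of both the pachytene and pre-meiotic values, -0.029 and -0.020, did not stand apart. The pre-meiotic X value also did not stand apart without multicopy families (-0.020, percentile 4.45), without subtraction of the autosomal median (-0.026, percentile 2.51) and at implied errors of at most 0.5 (-0.017, percentile 4.96). The erythrocyte list in the pre-meiotic table turned from 0.71 to -0.085 as a mean. The cause of these changes in the X and list values was not tested. For list medians under these settings, 176 results that stood apart and 264 that did not kept their sign and side of the limits, 18 no longer stood apart, 15 newly did so, and 1 that stood apart turned, as given. Another 24 turned without standing apart. As means these were, at pachytene, the Argonaute (-0.061), leptotene and zygotene (-0.043) and pachytene lists (-0.037), and at leptotene/zygotene the Argonaute (-0.11), leptotene and zygotene (0.017), spermatid (-0.054), Y-linked (-0.012) and X-linked housekeeping lists (0.11). Further means were 0.028 for the pre-meiotic Argonaute list and, at day 3, retinoic acid (-0.079), Leydig (0.0084), myoid (-0.037), erythrocyte (-0.24) and endothelial lists (-0.030). At implied errors of at most 0.5 they were the X-linked housekeeping list at pachytene (-0.079), the Argonaute (-0.24), undifferentiated spermatogonia (0.10), Y-linked (-0.26), p53 (0.15) and cell cycle lists (-0.034) at leptotene/zygotene, the pre-meiotic undifferentiated list (-0.00044), and the pachytene (0.048) and spermatid lists (0.13) at day 3. With infinite ratios kept it was the pre-meiotic histone list (0.020). Centring moved no Ago4 fold by more than its implied error and no count of 2-fold different genes by over 1.5 times. Settings that need FPKM, namely floors, pseudocounts, upper-quartile scaling and levels per library, were not run, nor was the removal of pseudoautosomal genes. Only rows the authors tested were used, so the planned contrast with all rows was not run. No paired analysis was possible because the conditions carry no genotype, so the labels do not let the direction of a difference be matched between stages. Signs can be compared only as coded, as for the 111 calls shared by the spermatocyte tables, all of the same sign. Depth is unknown, and in the simulations 2-fold changes were called in only 41% of cases at pachytene, so an uncalled gene is not shown to be unchanged.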

Other observations

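A few genes differed in 3 or 4 tables. These genes, and the tests on windows around Ago4 and between shared genes, were chosen after the values were seen. Called in 3 tables were 37 genes, 20 of them with the same sign in all 3 as coded, and called in all 4 were 3 genes. Ndufs5, of respiratory complex I (chromosome 4, 123389953 to 123395445), had log2 folds of 2.55, 2.32, 3.08 and 1.58 in the authors' deposited table for pachytene, leptotene/zygotene, pre-meiotic and day 3 material. The histone deacetylase gene Hdac1 (chromosome 4, 129193348 to 129219957) was at 1.28, 1.16, 1.05 and 0.63 in the authors' deposited table for the same stages. Rpl29 (chromosome 9, 106331785 to 106333899) was at 2.79, 2.63, 3.58 and, with the opposite sign, -2.48 in the authors' deposited table for the same stages, and genes of ribosomal proteins have many processed copies that share reads. Tex15, Sycp2 and Smc1b, all of meiosis, were called lower in the pachytene, pre-meiotic and day 3 tables, with -1.54, -0.59 and -1.19 for Tex15 in the authors' deposited table, and were not called at leptotene/zygotene. All 3 have long loci, of at least 60610 bp. The longest loci had medians of -0.045 at pachytene and -0.42 at day 3, and log2 fold did not fall with span in the pre-meiotic table. Whether span accounts for these calls was not tested.

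Ndufs5 and Hdac1 lie within 5 Mb of Ago4 on chromosome 4. Within 10 Mb of Ago4, leaving out Ago4 itself, 13 of 392 genes were called at pachytene (3.32%, against a median of 1.44% in windows of that width around random genes, percentile 88.9), 9 of 340 at leptotene/zygotene (2.65%, percentile 67.6), 10 of 373 in the pre-meiotic table (2.68%, percentile 89.5) and 82 of 445 at day 3 (18.4%, percentile 82.1). None of these shares lay outside the limits, and with 5 Mb on each side the percentiles were 93.8, 91.5, 94.1 and 86.7. A share over all genes of a window cannot exclude a difference limited to a few genes near Ago4. Ndufs5 and Hdac1 are among the 3 genes called in all 4 tables, and their place near Ago4 was not tested on its own. The 111 genes called in both spermatocyte tables fell in 18 windows of 5 Mb that held at least 2 of them, against a median of 14 for random genes matched on implied error (percentile 92.8). This count does not weigh how many genes a window holds. Chromosome 17 held 4 at 30 to 35 Mb (Rps18, Dom3z, C4b and H2-Ab1) and 3 at 35 to 40 Mb (Olfr112, Hspa1b and Hspa1a). Chromosome 2 held 4 at 150 to 155 Mb, and chromosome 4 held 3 at 125 to 130 Mb (Phc2, Hdac1 and Eif2c4). These windows were not tested singly.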
